A study of Mus musculus with 8 samples.

How the data were processed

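RNA abundance was measured in CD8+ T cells purified from mouse spleen, either wild type (C57BL/6) or lacking the transcription factor gene Elf4, on Affymetrix oligonucleotide arrays. Cells were taken without stimulation, called naive here, or after 3.5 days on plates carrying antibody to CD3 with antibody to CD28 in the medium, called activated here. Each of the 4 combinations of genotype and state had 2 arrays, 8 in all, and the group and replicate number of each array came from the sample titles. The labels do not say that the replicates were separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

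The authors deposited 1 intensity per probe set and array on a linear scale. MAS5 made these values per the submitters' processing notes, and its version is not given in the sources used here. In the deposited table every array had a 2% trimmed mean intensity of 500, there were 0 missing values and 0 values at or under 0, so each array had already been scaled by the authors. Detection calls were not used here. The number of arrays, 2 per group, limits the precision.

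The table held 45101 probe sets, of which 64 were manufacturer's controls. Gene symbols came from the platform's annotation: 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Symbols were updated through Entrez identifiers against a gene table of the assembly GRCm38.p6, which matched 34754 of the 34958, and 204 kept the platform's symbol. That assembly was used for symbols and for the order of genes along chromosomes. No gene was named from a probe set with several symbols or none.

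All computing was done in R 4.3.3 with limma 3.58.1. Values were taken as log2(intensity + 16), so a log2 fold change understates the change of dim genes. A probe set was tested if it was at or above the array's median on at least 2 of the 8 arrays, which kept 27348 probe sets for 12823 named genes, 5790 of which had over 1 probe set. No further scaling between arrays was applied. A linear model with 4 group means was fitted to all 8 arrays with lmFit and eBayes (trend=TRUE), leaving 4 residual degrees of freedom with a prior of 6.7. The 5 contrasts were knockout against wild type in naive cells, knockout against wild type in activated cells, activated against naive cells in each genotype, and the difference of the genotype effect between the states. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a contrast, and the threshold was an adjusted p of 0.05. Values before a ± are means of intensity and values after it are SDs of 2 arrays.

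There were 31 gene lists, written from textbook knowledge of T cells and of the other cell types a spleen preparation could hold. Of their 740 entries 682 had a named probe set, and the others were not analysed here. The 30 lists with at least 5 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, with 1 probe set per gene, the brightest over all arrays, and with adjustment over the lists within a contrast. Each call was repeated with a correlation estimated from the residuals and with fry, which tests whether the members move one way on balance and does not compare them with other genes. Camera with an estimated correlation tests on the 4 residual degrees of freedom, so it can lose a call where genes are uncorrelated. The lists, the design, the rule for named genes and the alternatives were fixed before the data were examined, apart from the alternatives said to have been added.

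Named genes followed a rule. It took Elf4, a set of genes that the study is known to have followed, and per contrast the 12 genes with the largest rise and the 12 with the largest fall among probe sets past the threshold with 1 symbol and array values that do not overlap between the groups. It took 6 of each for the difference between states and up to 4 members of each list with the smallest p. Where a gene had several probe sets past the threshold, the brightest was used.

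The alternatives were no offset with values under 1 set to 1, an offset of 64, quantile normalization, centring each array on its median, no filter, a filter at 6 of 8 arrays, eBayes without a trend or with robust estimation, a fit to the 4 arrays of a comparison, array weights, the replicate number or the title label as a block, an additional log2 fold change of at least 1, and leaving out each array in turn. An array left alone in its group was assumed to vary like the other groups. After the data were seen, the log2 of the Actb 3'/5' signal ratio as a covariate, the removal of probe sets that may cross-hybridise (identifiers ending in _x_at or _s_at) and a crossed replicate block were added. The replicate numbers were not taken as pairs.

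The fit was tested on simulated data made from the arrays' own means and spread over 27348 probe sets, with 100 probe sets changed at each of 2 sizes. The noise was drawn independently for each probe set, with the same spread in all 4 groups. In the data the residual SD was 0.514 for the naive and 0.435 for the activated arrays fitted alone. The rates below therefore do not cover an unequal spread between the states. In the naive comparison 24% of the probe sets changed by 1 on the log2 scale and 67% of those changed by 2 were recovered, and 7.1% of the calls were false. In the activated comparison the shares were 20% and 55%, with 5.1% of calls false. For lists an unadjusted p under 0.05 counted as a call here, whereas the list calls in the data used adjusted p-values. On that basis camera at the preset correlation called 16 of 500 unshifted lists (3.2%) in the naive and 8 of 500 (1.6%) in the activated comparison. It called 20 of 20 lists of 30 members shifted by 0.5 on the log2 scale in each. These random lists had no correlation between genes, so the rates do not apply to correlated lists. In the data the estimated correlation was 0.086 for mitotic and for immediate early genes, 0.284 for granulocyte and 0.54 for B cell markers.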

Results

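The data comprised 8 arrays, 2 each for naive wild-type, naive Elf4 knockout, activated wild-type and activated Elf4 knockout CD8+ T cells. Array medians lay between 63.9 and 86.0 intensity units. Across probe sets, which are not independent replicates, the 4 replicate pairs correlated at 0.94 to 0.965. The 8 pairs of the same state and different genotype correlated at 0.936 to 0.959 and the 16 pairs of different states at 0.799 to 0.831, so the state separated the arrays far more than the genotype did. The 0.94 was that of the wild-type naive replicates, while naive arrays of different genotype correlated at 0.942, 0.948, 0.948 and 0.936. The wild-type naive replicates thus differed about as much as naive arrays of different genotype did.

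Elf4, an X-linked gene of the ETS family and the gene disrupted in the knockout, gave low intensities throughout. Its brighter probe set read 116 and 198 in naive wild-type, 165 and 192 in naive knockout, 83.6 and 134 in activated wild-type, and 76.2 and 80.6 in activated knockout cells. Its dimmer probe set read 32.4 and 9.37, 77.6 and 58.2, 112 and 58.5, and 1.93 and 26.1 in the same order. Neither differed by genotype in naive cells (adjusted p = 0.891 and 0.522) or in activated cells (adjusted p = 0.813 and 0.373). Whether these probes lie in the deleted part of the gene was not analysed here, so Elf4 does not check the genotype labels.

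Other measures separated the naive from the activated arrays. Xist, the RNA that coats the inactive X chromosome, read 60.3 to 172 on naive and 7703 to 10010 on activated arrays, while the Y-linked gene Eif2s3y read 2537 to 5146 and 2.93 to 44.0. The naive samples thus had the pattern of male and the activated samples that of female cells. The Lys spike-in control read 49.6 to 73.0 on naive and 52457 to 59027 on activated arrays. The signal ratio of the 3' to the 5' probe set of Actb, a measure of RNA integrity, was 1.96 to 2.5 on naive and 5.9 to 11.1 on activated arrays. Below, RNA integrity stands for this ratio. Whether the state of the RNA or the preparation of the samples set the ratio was not tested. The array-file labels of naive and activated samples also belong to different series. Sex, array series, spike-in level, RNA integrity and activation therefore cannot be told apart here.

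The comparison of naive cells asked which genes depend on Elf4 in resting CD8+ T cells, in a study of the control of their proliferation. Klf4, a Krüppel-like factor gene that restrains T cell division, was 5.58-fold lower in the knockout (419 ± 165 against 2378 ± 730, SD, n = 2). It fell by 2.48 on the log2 scale (SE 0.31, adjusted p = 0.0119). Of 35 immediate early genes 14 fell, among them Jun, a subunit of the AP-1 transcription factor, though the list's call was lost with an estimated correlation (adjusted p = 0.0956). Mki67, which encodes the proliferation marker Ki-67, rose 3.81-fold from 214 ± 57.3 to 860 ± 206 (log2 1.93, SE 0.20, adjusted p = 0.00427). It was among 7 of 50 mitotic genes that rose, a list whose call was also lost (adjusted p = 0.188 with an estimated correlation). With fry the immediate early and mitotic lists passed (adjusted p = 0.0216 and 0.0226). The granulocyte genes S100a8, S100a9, Ngp and Lcn2 and the immunoglobulin gene Igha rose by over 4 on the log2 scale, calls that were lost without knockout naive replicate 2.

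**Figure D1:**
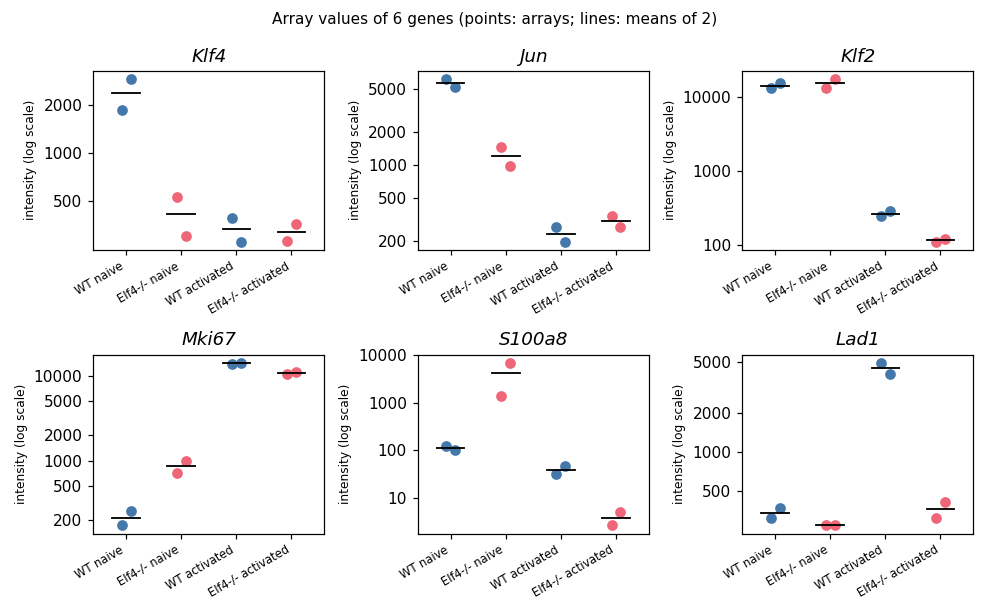
Intensity on each of the 8 arrays, on log scales, for Klf4, Jun, Klf2, Mki67, S100a8 and Lad1, with 1 point per array (blue for wild type, red for knockout) and lines at the means of 2. Klf4 and Jun were lower and Mki67 and S100a8 higher in naive knockout cells, S100a8 with a wide gap between its 2 knockout arrays, while Klf2 and Lad1 were lower in activated knockout cells.

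In naive cells 154 of 27348 probe sets passed the threshold, 86 higher and 68 lower in the knockout, and they named 128 genes. The change was at least 2-fold for 126 of the 154 probe sets. An unadjusted p under 0.05 was found for 3310 probe sets, where 1367 were expected by chance. The knockout and wild-type values did not overlap for 38.2% of probe sets, against 33.3% by chance. With each array centred on its median, which moved the median of all probe sets to 0.10 on the log2 scale, 72.7% of the calls were higher, against 55.8% as reported. The limma count was 5, for 2 named genes, in a fit of the 4 naive arrays alone, 3 without a trend in the prior variance, 57 with array weights, 102 without a filter and 18 with the Actb ratio as a covariate. It was 28 without knockout naive replicate 2, 27 without either wild-type activated array, 35 without either knockout activated array and 235 without knockout naive replicate 1.

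Among the largest rises in naive knockout cells were genes of other blood cells. Igha, the constant region of immunoglobulin A, rose from 382 ± 344 to 11090 ± 4610 (log2 5.07, adjusted p = 0.0183). S100a9 and S100a8, the subunits of neutrophil calprotectin, rose by 4.83 and 4.60 (adjusted p = 0.0171 and 0.0136). S100a8 read 4147 with an SD of 3950 in the knockout. The granule genes Ngp and Lcn2 rose by 4.36 and 4.61 (adjusted p = 0.0132 and 0.0392). Ighm, the heavy chain of immunoglobulin M, rose by 3.44 on 1 of its 7 probe sets (adjusted p = 0.0379), while the brightest of them gave −0.40 (adjusted p = 0.225). Klra8, an NK cell receptor gene, rose by 2.60 (adjusted p = 0.0493). Without knockout naive replicate 2, none of Igha, S100a9, Lcn2, S100a8, Ngp, Ighm and Klra8 passed, with changes from 2.55 for Ighm to 4.64 for Igha. The calls of Lcn2, Ighm and Klra8 were kept in 7 of 21, 8 of 21 and 6 of 20 alternatives, and those of Ngp, S100a9, S100a8 and Igha in 18 of 22, 16 of 21, 14 of 20 and 14 of 21. Further rises were those of Sgo1, which protects the cohesion of centromeres, by 2.69 (adjusted p = 0.00819), Nacc2, a transcriptional repressor, by 3.31 (adjusted p = 0.042), and Hmgn3, a nucleosome-binding protein, by 2.41 (adjusted p = 0.042). Wdr53, a WD-repeat protein, and 2610316D01Rik rose by 2.27 and 3.01 (adjusted p = 0.0269 and 0.0487). These 5 calls were also lost without knockout naive replicate 2, and those of Nacc2 and 2610316D01Rik were kept in 5 of 21 alternatives.

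The largest fall of a named gene was that of Erdr1, from 13790 ± 5410 to 190 ± 23.6 (log2 −6.01, SE 0.28, adjusted p = 9.5e-06). The log2 change was −2.33 for Ppp1r15a, a phosphatase subunit that restores translation after stress, and −2.23 for Jun (adjusted p = 0.008 and 0.0058). Nr4a2, an orphan nuclear receptor, changed by −2.10 and Rgs1, a regulator of G protein signalling, by −1.97 (adjusted p = 0.00615 for both). Dusp1, a phosphatase acting on MAP kinases, dropped from 15720 ± 4000 to 4227 ± 1570 (log2 −1.92, adjusted p = 0.0136). Plk2, a polo-like kinase, fell by 2.18 and S100a1, a calcium-binding protein, by 1.99 (adjusted p = 0.0249 and 0.0252). Orc1, the large subunit of the origin recognition complex, fell by 2.36 on a dim probe set (125 to 11.5, adjusted p = 0.0249), while its brightest probe set did not pass. The synaptic gene Cplx1 changed by −2.70 and the podosome adaptor Sh3pxd2b by −2.36 (adjusted p = 0.026 and 0.0493), while their other probe sets went the opposite way. The Sh3pxd2b call was kept in 2 of 22 alternatives and lost without any of the 8 arrays, and the Cplx1 call was kept in 11 of 22. The calls of Orc1, Plk2 and S100a1 were kept in 10 of 22, 12 of 22 and 11 of 21. The other Klf4 probe set gave −0.49 (adjusted p = 0.862). The Klf4 call kept its direction in 22 of 22 alternatives and its significance in 18. It was lost without a trend (adjusted p = 0.148), with the 4 naive arrays alone (0.138), without knockout naive replicate 2 (−2.08, 0.0635) and with the Actb ratio as a covariate (−2.27, 0.0677). The Mki67 call was lost without a trend (adjusted p = 0.13) and with the 4 naive arrays alone (0.213), as were those of Jun and Rgs1.

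Other genes that the study is known to have followed did not pass in naive cells. Klf2, a Krüppel-like factor of quiescence and homing, gave 0.11 (14220 ± 1640 and 15470 ± 2970, adjusted p = 0.872). Ccr7, the lymph node homing receptor, gave −0.27 (adjusted p = 0.487). S1pr1, the receptor for exit from lymphoid organs, gave 0.04 (adjusted p = 0.965) and Il7r, the interleukin 7 receptor, 0.15 (adjusted p = 0.662). The adhesion receptor gene Cd44 gave 0.08 (adjusted p = 0.931) and the cell cycle inhibitor gene Cdkn1a −0.95 (adjusted p = 0.191).

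Of the 30 lists tested in naive cells, 10 passed camera with the preset correlation and 0 with an estimated correlation, while fry called 5. Those 5 were the immediate early, mitotic, interferon-stimulated, innate-like and CD4 lists (fry adjusted p = 0.0216, 0.0226, 0.0216, 0.041 and 0.041). The estimated version lost calls even where the estimate lay under the preset 0.01. For the innate-like list the estimate was −0.018, and the unadjusted camera p went from 0.0011 to 0.0245. A call lost in that version thus need not mean that correlation between the genes undid it. Of 35 immediate early and dissociation stress genes, 14 fell and none rose (23 fell when adjusted over the list alone). Their median was −1.12 (adjusted p = 8.62e-26, and adjusted p = 0.0956 with an estimated correlation). Members included Tnfaip3, an inhibitor of NF-κB signalling (−1.88, adjusted p = 0.00637), Nr4a1 (−1.75, 0.0493) and the early activation marker Cd69 (−1.22, 0.0171). Of 50 G2/M and mitosis genes, 7 rose (22 higher and 1 lower adjusted over the list alone), with a median of 0.72. This gave adjusted p = 1.93e-13, and adjusted p = 0.188 with an estimated correlation. Besides Mki67 they included the spindle midzone gene Prc1 (1.34, 0.0143), the checkpoint kinase Bub1b (1.89, 0.0143) and the topoisomerase Top2a (1.35, 0.0171). Of 52 DNA replication and G1/S genes 1 rose, the ribonucleotide reductase subunit Rrm2 (1.01, 0.0132), and 2 were higher adjusted over the list alone. That list had a median of −0.01, a mean of 0.15 and an upward test of adjusted p = 0.619.

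Markers of other cell types were higher beside these groups in naive knockout cells. Of 15 granulocyte markers 4 rose, namely Ngp, S100a8, S100a9 and Lcn2 (7 adjusted over the list alone), with a median of 1.06. This gave adjusted p = 1.45e-06, and adjusted p = 0.327 with an estimated correlation. The mean log2 level of these markers was 6.07 and 6.52 in the wild-type and 7.79 and 8.93 in the knockout arrays. Of 12 NK cell markers 1 rose, Klra8 (7 adjusted over the list alone), with a median of 1.04 (adjusted p = 8.22e-06, and adjusted p = 0.259 with an estimated correlation). No member of the other passing marker lists passed alone. The 20 macrophage and monocyte markers had a median of 0.72 (adjusted p = 0.0015, and adjusted p = 0.439 with an estimated correlation), with Fcgr3 at 2.12 (adjusted p = 0.199). The 23 B cell markers had a median of 0.55 (adjusted p = 0.0269, and adjusted p = 0.71 with an estimated correlation). Without knockout naive replicate 2 the B cell median was −0.17, and neither that list nor the macrophage list passed. The Actb ratio was 2.13 and 2.5 in wild-type and 1.99 and 1.96 in knockout naive arrays.

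Smaller shifts passed in 4 further lists of naive cells. The 17 innate-like memory phenotype genes had a median of 0.45 (adjusted p = 0.00435, and adjusted p = 0.188 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. They included the NK receptor gene Klrc1 (1.30, adjusted p = 0.0735), the transcription factor Tbx21 (0.76, 0.0754) and Ifng (−1.35, 0.0981). Of 37 interferon-stimulated genes 1 rose, the GTPase Igtp (0.83, adjusted p = 0.0332), and 3 adjusted over the list alone. The median was 0.22 (adjusted p = 0.0015, and adjusted p = 0.188 with an estimated correlation). The 37 ribosome biogenesis genes had a median of −0.15 (adjusted p = 0.00435, and adjusted p = 0.439 with an estimated correlation), with 2 lower adjusted over the list alone. The 33 mitochondrial respiratory chain genes had a median of −0.08 (adjusted p = 0.00499, and adjusted p = 0.55 with an estimated correlation). Each of these 4 lists, and the macrophage and B cell lists, lost its call without wild-type naive replicate 1, where 4 lists passed in all.

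The lists that name the study's question did not pass camera in naive cells. The 24 quiescence factors, of which Klf4 fell (2 lower adjusted over the list alone), had a median of 0.07, a mean of −0.11 and a downward test of adjusted p = 0.605. The 23 homing and trafficking genes had a median of 0.04, a mean of 0.05 and a downward test of adjusted p = 0.987. The 9 CDK inhibitors and pocket proteins had a median of 0.13 (adjusted p = 0.408) and the 9 G1 cyclins and their kinases one of −0.17 (adjusted p = 0.374). The 20 naive and memory T cell genes had a median of −0.01, a mean of 0.02 and adjusted p = 0.963. The 29 T cell receptor complex and signalling genes had a median of −0.02 (adjusted p = 0.553) and 22 activation and costimulatory receptors a median of 0.08, a mean of −0.05 and adjusted p = 0.963. The 28 cytotoxic effector genes had a median of 0.18 (adjusted p = 0.302) and 28 effector and memory transcription factors one of 0.16 (adjusted p = 0.374), with Nr4a2 and Nr4a1 lower. Of 11 inhibitory receptors, Pdcd1, which encodes PD-1, rose by 1.56 (adjusted p = 0.0301), with a list median of 0.24 (adjusted p = 0.374). Of 9 CD4 and regulatory T cell markers, the Helios gene Ikzf2 (1.88, adjusted p = 0.0013) and Gpr83 (2.10, 0.0493) rose, with a list median of 0.32 (adjusted p = 0.0722).

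Metabolic and other lists in naive cells also did not pass. Glycolysis gave a median of −0.01 and a mean of 0.02 (adjusted p = 0.605), cholesterol and fatty acid synthesis −0.13 (0.325), apoptosis regulators 0.09 (0.25), ETS family genes −0.01 (0.746) and the X-linked neighbours of Elf4 0.03 (0.746). Dendritic cell markers gave 0.24 (0.374), erythroid markers −0.09 with a mean of 0.07 (0.979) and platelet markers −0.30 (0.365).

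The comparison of activated cells asked which genes depend on Elf4 after 3.5 days of stimulation. Klf2 was 2.14-fold lower in the knockout (114 ± 6.63 against 263 ± 30, SD, n = 2; log2 −1.10, SE 0.18, adjusted p = 0.0464), while Klf4 was level at 324 ± 55.7 and 336 ± 78.6 (adjusted p = 0.983). The chemokine genes Xcl1 and Ccl3 fell and the cytokine gene Il24 rose 3.68-fold. Of 37 interferon-stimulated genes 1 fell, and the lower list median passed with the preset but not with an estimated correlation (adjusted p = 0.118). That list passed with fry (adjusted p = 0.017). Lad1, an anchoring filament protein gene that wild-type cells raised on activation, was 12-fold lower in activated knockout cells.

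In activated cells 59 probe sets passed, 31 higher and 28 lower in the knockout, naming 44 genes. The change was at least 2-fold for 46 of the 59 probe sets. An unadjusted p under 0.05 was found for 2878 probe sets, where 1367 were expected by chance, and values did not overlap for 47% of probe sets, against 33.3% by chance. A fit of the 4 activated arrays alone called 734, 451 higher and 283 lower, including 58 of the 59. With each array centred on its median 31 passed, 64.5% of them higher, against 52.5% as reported. The limma count was 438 with array weights, 92 with robust estimation, 26 with the replicate number as a block, 7 without a trend and 6 with the Actb ratio as a covariate. It was 94, 103 and 91 without wild-type naive replicate 1, wild-type naive replicate 2 and knockout naive replicate 1. It was 8 and 19 without wild-type activated replicates 1 and 2, and 17 and 14 without knockout activated replicates 1 and 2.

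Among the rises, Scd2, a stearoyl-CoA desaturase, went from 249 ± 67.9 to 4735 ± 127 on 1 of its 3 probe sets (log2 4.19, SE 0.41, adjusted p = 0.00162). That probe set rose by 3.59 in naive cells, whereas the brightest Scd2 probe set gave 0.34 in activated (adjusted p = 0.635) and 1.22 in naive cells (adjusted p = 0.0362). Ap1s3, an adaptor subunit of clathrin vesicles, rose by 2.48 (adjusted p = 0.00162) and Wdfy1, an endosomal protein, by 2.09 (adjusted p = 0.0247). Tgm2, a transglutaminase, rose by 2.13 (adjusted p = 0.0147), and Il24, an interleukin 10 family cytokine, from 964 ± 130 to 3575 ± 119 (log2 1.88, adjusted p = 0.0159). The phosphatase Ptpn13 rose by 2.53 and the small adaptor gene Bex1 by 1.72 (adjusted p = 0.0452 and 0.0495). The kinesin Kif5c rose by 1.59, the semaphorin Sema4f by 1.56 and the actin-severing protein gelsolin, Gsn, by 1.54 (adjusted p = 0.0328, 0.00358 and 0.0254). The ubiquitin ligase Siah1a rose by 1.34 and Basp1, a membrane-attached signal protein, by 1.23 (adjusted p = 0.0247 and 0.037). Other probe sets of Ptpn13 and Siah1a went the opposite way.

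The falls were led by Erdr1, from 9197 ± 1150 to 146 ± 47.0 (log2 −5.85, SE 0.28, adjusted p = 1.25e-05), and Lad1, from 4486 ± 637 to 360 ± 71.0 (log2 −3.59, SE 0.22, adjusted p = 3.42e-05). Calhm6, a calcium channel subunit, fell by 2.73 (adjusted p = 0.00229). Uri1, a prefoldin-like protein, and Pop4, a subunit of ribonuclease P, fell by 2.02 each (adjusted p = 0.004 and 0.00163), although the other Uri1 probe sets went the opposite way. The interferon-inducible genes Mndal and Ifi209 were lower, at −1.91 and −1.58 (adjusted p = 8.58e-05 and 0.0118). The chemokine genes fell by 1.55 for Xcl1 (2843 ± 862 to 944 ± 158, adjusted p = 0.0347) and 1.40 for Ccl3 (8471 ± 2430 to 3160 ± 440, adjusted p = 0.0464). Thap4, Rnpep, an aminopeptidase, and Galnt12, a glycosyltransferase, gave −1.73, −1.46 and −1.25 (adjusted p = 0.0242, 0.0256 and 0.0245). The Klf2 value ranged from −1.26 to −0.87 over 21 alternatives and passed in 9 of them. It was lost with an offset of 64, quantile normalization, median centring, no filter, no trend, 4 arrays or the replicate number as a block, without any of the 4 activated arrays, and with the Actb ratio as a covariate (highest adjusted p = 0.692). Leaving out a single activated array ended most calls of the comparison, whereas Erdr1, Lad1, Calhm6 and Mndal passed without each of the 8 arrays.

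Other followed genes did not pass in activated cells. Cd44 gave 0.71 (10390 ± 1200 and 16920 ± 697, adjusted p = 0.272), Mki67 −0.37 (13950 ± 338 and 10790 ± 294, adjusted p = 0.577) and Cdkn1a 0.47 (adjusted p = 0.597). Ccr7 gave −0.23 (adjusted p = 0.614), S1pr1 0.35 (0.584) and Il7r 0.33 (0.288).

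**Figure D2:**
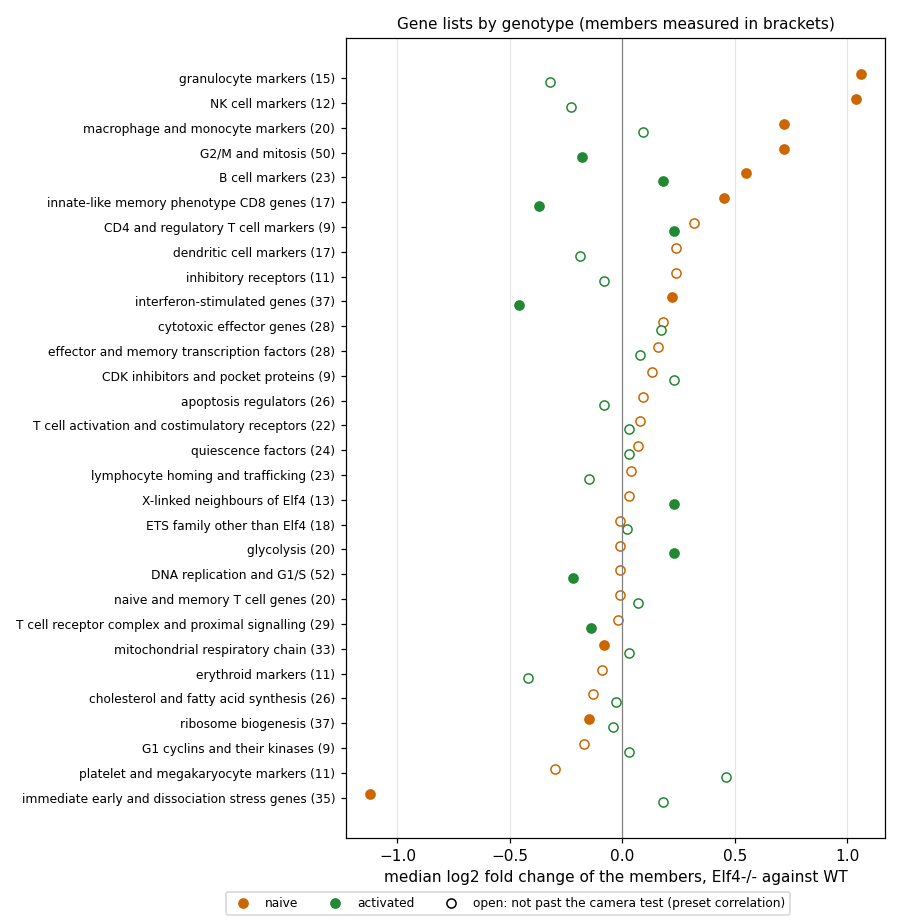
Median log2 fold change of knockout against wild type for the 30 tested gene lists, in naive (orange) and activated cells (green), with the number of measured members in brackets. Filled points passed camera with the preset correlation and open points did not; no list passed with an estimated correlation. Immediate early genes lay lowest in naive cells (−1.12), and interferon-stimulated genes lay lowest in activated cells (−0.46).

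In activated cells 9 of 30 lists passed camera with the preset correlation, 0 with an estimated correlation and 2 with fry. Those 2 were the interferon-stimulated genes and the X-linked neighbours of Elf4 (fry adjusted p = 0.017 for both). Of 37 interferon-stimulated genes, Gbp2, an interferon-induced GTPase, fell (−1.10, adjusted p = 0.0254), and 13 were lower and 1 higher adjusted over the list alone. The median was −0.46 (adjusted p = 1.82e-08, and adjusted p = 0.118 with an estimated correlation). Zbp1, a sensor of nucleic acids, gave −1.24 (adjusted p = 0.111) and the exonuclease gene Isg20 −1.73 (adjusted p = 0.142). No member of the DNA replication list passed alone. The list had a median of −0.22 (adjusted p = 0.000283, and adjusted p = 0.214 with an estimated correlation), with 2 lower adjusted over the list alone and Dnmt1, the maintenance methyltransferase, at −0.60 (adjusted p = 0.122). The 50 mitotic genes had a median of −0.18 (adjusted p = 0.0336, and adjusted p = 0.694 with an estimated correlation). The 20 glycolysis genes had a median of 0.23 (adjusted p = 0.000436, and adjusted p = 0.324 with an estimated correlation), with 2 higher adjusted over the list alone and the glucose transporter Slc2a3 at 0.66 (adjusted p = 0.215). Of 17 innate-like genes 1 fell, Xcl1, while 2 were higher and 6 lower adjusted over the list alone. Their median was −0.37 (adjusted p = 0.0396, and adjusted p = 0.324 with an estimated correlation), with Klrd1 at −0.74 (adjusted p = 0.0891).

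The remaining passing lists in activated cells were these. Of 29 T cell receptor and signalling genes 1 fell, the kinase gene Prkcq (−0.82, adjusted p = 0.0365), and 1 was higher and 4 lower adjusted over the list alone. The median was −0.14 (adjusted p = 0.0186, and adjusted p = 0.324 with an estimated correlation), with Cd3e at −0.76 (adjusted p = 0.114). The 13 X-linked neighbours of Elf4 had a median of 0.23 (adjusted p = 0.013, and adjusted p = 0.303 with an estimated correlation), with 4 higher adjusted over the list alone and Rab33a at 1.39 (adjusted p = 0.0976). The 23 B cell markers had a median of 0.18 (adjusted p = 0.013, and adjusted p = 0.854 with an estimated correlation), with 6 higher adjusted over the list alone and H2-Aa at 1.30 (adjusted p = 0.0803). Of 9 CD4 and regulatory T cell markers 1 rose, Ikzf2 (0.97, adjusted p = 0.046), with a list median of 0.23 (adjusted p = 0.0336, and adjusted p = 0.324 with an estimated correlation). In these activated arrays the Actb ratio was 5.98 and 5.9 in wild type against 7.44 and 11.1 in the knockout, and with it as a covariate the mitotic, innate-like, T cell receptor, X-linked and CD4 list calls were lost (adjusted p = 0.206, 0.0951, 0.206, 0.0951 and 0.178). Their medians with it were −0.21, −0.38, −0.10, 0.15 and 0.21, against −0.18, −0.37, −0.14, 0.23 and 0.23 without it. The mitotic call was also lost without any of the 4 activated arrays and kept in 9 of 17 alternatives, and the innate-like call was kept in 7 of 17. The B cell call was lost without probe sets that may cross-hybridise, the T cell receptor call without wild-type activated replicate 1, and the CD4 call without replicate 1 of either activated group (kept in 10 of 17).

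The other 21 lists did not pass in activated cells. Quiescence factors, with Klf2 lower, gave a median of 0.03 (adjusted p = 0.815) and homing genes a median of −0.15, a mean of 0.01 and adjusted p = 0.369. CDK inhibitors gave 0.23 (0.588), G1 cyclins 0.03 (0.847), and naive and memory genes 0.07 (0.588; 3 higher and 3 lower adjusted over the list alone). Cytotoxic genes gave 0.17 (0.865), with Xcl1 and Ccl3 lower. Effector transcription factors gave 0.08 with a mean of −0.05 (0.865), and costimulatory receptors gave 0.03 with a mean of −0.02 (0.815; 4 higher and 4 lower adjusted over the list alone). Inhibitory receptors gave −0.08 (0.588), cholesterol and fatty acid synthesis −0.03 with a mean of 0.02 (0.865), ribosome biogenesis −0.04 (0.251) and mitochondrial genes 0.03 (0.589). Immediate early genes gave 0.18 (0.0704), with Ier3, a stress-induced survival gene, 1.04 higher (adjusted p = 0.0256). Apoptosis regulators gave −0.08 in an upward test (0.95) and ETS family genes 0.02 (0.95). Marker lists gave −0.23 for NK cells (0.865), 0.09 for macrophages (0.592), −0.32 for granulocytes (0.251), −0.42 for erythroid cells (0.588) and 0.46 for platelets (0.0826). Dendritic cell markers gave −0.19 with a mean of 0.17 (0.365).

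Activated and naive cells were compared within each genotype, and in both comparisons sex, array series and RNA integrity change together with activation. Il2ra, the high-affinity interleukin 2 receptor, rose from 39.7 ± 7.84 to 12660 ± 580 in wild-type cells (log2 7.84, SE 0.18, adjusted p = 3.64e-09) and by 7.47 in the knockout. The granzyme gene Gzmb reached 53110 ± 2350 in wild-type and 59150 ± 5970 in knockout cells (log2 7.69 and 6.92). Klf2 fell from 14220 ± 1640 to 263 ± 30 in wild-type cells (log2 −5.67, SE 0.18, adjusted p = 2.3e-08) and from 15470 ± 2970 to 114 ± 6.63 in the knockout (log2 −6.88, adjusted p = 6.61e-09). Klf4 fell by 2.75 in wild-type cells (adjusted p = 4.95e-05) and gave −0.31 in the knockout (adjusted p = 0.467), a difference of 2.44 that did not pass its own test (adjusted p = 0.0934). Mitotic and replication genes rose and quiescence and homing genes fell in both genotypes.

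On activation 10714 probe sets passed in wild-type cells, 4757 higher and 5957 lower, for 6591 genes, and 11395 in the knockout, 4976 higher and 6419 lower, for 6952 genes. The values did not overlap for 68.7% and 71.5% of probe sets, against 33.3% by chance. Of these, 8502 passed in both genotypes, 8483 with the same sign and 19 with opposite signs, where independent lists would share 2264 with the same sign. The log2 fold changes correlated across probe sets at r = 0.843 and rho = 0.796, and the contrasts shared no array. Another 2212 passed in wild type alone and 2893 in the knockout alone. The median over all probe sets was −0.155 and −0.159, against −0.032 and −0.039 after quantile normalization and 0.035 and −0.039 with median centring. Of the wild-type calls 44.4% were higher as reported and 55.2% with median centring. With the Actb ratio as a covariate, which nearly follows the state, limma called 484 in wild type and 0 in the knockout, where 2622 had an unadjusted p under 0.05.

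In wild-type cells the rises of the named genes were led by Cth, which makes cysteine from cystathionine (7.94), Il2ra, Gzmb and Cdkn1a (7.32), with adjusted p from 3.64e-09 to 3.94e-08. Next came Lrr1 (6.91), the Schlafen gene Slfn3 (6.74), Svs5 (6.64), the asparagine synthetase Asns (6.33), the granzyme gene Gzmc (6.33), AA467197 (6.33), the checkpoint kinase Bub1 (6.31) and the centrin Cetn4 (6.21). The falls included the Y-linked Eif2s3y (−7.92), the gut-homing receptor Ccr9 (−7.32, from 7803 ± 1050 to 36.1 ± 26.0) and the surface protein Cd7 (−6.59). Gm11346 (−6.37), the monocarboxylate transporter Slc16a5 (−6.02), Smim27 (−5.38), the Notch target Dtx1 (−5.33) and the AP-1 gene Fos (−5.27) followed. Dusp1 (−5.22), the steroid dehydrogenase Hsd11b1 (−5.20) and the neuropeptide receptor Vipr1 (−5.05) also fell. In the knockout the leading rises were Cdkn1a (8.75), Cth (8.67), Slfn3 (7.83), Il2ra, Il24 (6.94), Gzmb, Xist (6.90), Svs5 (6.83), the cytokine Lif (6.67), the lipoprotein receptor Vldlr (6.50), the transaminase Gpt2 (6.38) and the cytokine Csf2 (6.21). The leading falls there were Ccr9 (−7.62), S100a8 (−7.29), Cd7 (−7.24), Igha (−7.15), Gm11346 (−6.95), Klf2, Mturn (−6.61), Calhm6 (−6.38), Baiap3 (−6.30), Hsd11b1 (−6.14), the interferon-induced Rtp4 (−6.11) and Eif2s3y (−6.10).

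Of the followed genes, S1pr1 fell in wild-type and knockout cells (−3.74 and −3.43), as did Ccr7 (−1.45 and −1.42) and Il7r (−1.95 and −1.76; highest adjusted p = 1.34e-05). Cd44 rose by 2.26 and 2.88 (adjusted p = 1.79e-05 and 2.76e-06). Mki67 rose by 5.94 to 13950 ± 338 in wild-type and by 3.64 to 10790 ± 294 in knockout cells (adjusted p = 2.67e-08 and 2.84e-07).

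Of 30 lists 15 passed camera with the preset correlation in wild-type and 17 in knockout cells, 8 and 7 with an estimated correlation, and 26 and 28 with fry. Of 50 mitotic genes 46 rose in each genotype, with medians of 4.42 and 3.39 (adjusted p = 1.78e-26 and 2.07e-21), for example the kinesin Kif2c at 5.27 and 4.05. Of 52 replication genes 47 and 44 rose (48 and 45 adjusted over the list alone), with medians of 2.11 and 1.77 (adjusted p = 3.01e-22 and 5.49e-18), for example Rrm2 at 6.04 and 5.11. Cholesterol and fatty acid synthesis rose in 22 of 26 members in each, with medians of 1.82 (adjusted p = 5.39e-11 and 6.34e-11), including the sterol enzymes Sqle (2.87 and 3.05) and Idi1 (3.65 and 3.90). Glycolysis rose in 15 and 16 of 20 members (15 and 18 adjusted over the list alone), with medians of 1.55 and 1.79 and hexokinase Hk2 at 4.47 and 5.29. Its adjusted p was 7.13e-09 and 1.38e-10, and adjusted p = 0.0699 and 0.055 with an estimated correlation. Ribosome biogenesis rose in 23 of 37 members in each (24 adjusted over the list alone), with medians of 0.76 and 0.75 (adjusted p = 2.75e-06 and 3.48e-06, and adjusted p = 0.103 and 0.106 with an estimated correlation). Of 9 G1 cyclins and kinases 7 rose in each (8 and 7 adjusted over the list alone), with medians of 0.74 and 0.80 and Cdk6 at 2.92 and 3.10 (adjusted p = 0.00127 and 0.000493, and adjusted p = 0.0699 and 0.055 with an estimated correlation). Of 22 activation and costimulatory receptors 14 and 15 rose and 5 and 6 fell (15 rose in each adjusted over the list alone), with medians of 1.2 and 1.31 and the costimulator Icos at 2.94 and 2.67. They had adjusted p = 0.000652 and 0.000493, and adjusted p = 0.0919 and 0.0876 with an estimated correlation.

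Other lists had lower medians after activation. Of 24 quiescence factors 20 fell in wild-type and 17 in knockout cells, with medians of −1.69 and −1.52 (adjusted p = 8.52e-09 and 9.31e-07), including Klf3 (−4.86 and −5.24). Of 23 homing genes 19 and 18 fell, with medians of −2.57 and −2.76 (adjusted p = 2.1e-08 and 9.16e-08), including the chemokine receptor Cxcr3 (−3.57 and −4.55) and the integrin Itgb7 (−3.09 and −3.18). Of 20 naive and memory genes 15 and 16 fell, with medians of −1.91 and −1.82 (adjusted p = 1.93e-07 and 9.36e-07, and adjusted p = 0.0426 and 0.0514 with an estimated correlation). Of 29 T cell receptor and signalling genes 23 and 22 fell, with medians of −1.29 and −1.40 (adjusted p = 2.47e-08 and 2.95e-08), including Cd3g (−2.74 and −2.57). Of 37 interferon-stimulated genes 26 and 33 fell (27 and 34 adjusted over the list alone), with medians of −1.34 and −1.72 (adjusted p = 8.07e-08 and 1.94e-12) and Ifit3 at −3.65 and −5.50.

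Markers of other cells also moved with activation. Of 23 B cell markers 21 and 20 fell, with medians of −2.67 and −3.0 (adjusted p = 8.07e-08 and 1.67e-07, and adjusted p = 0.344 and 0.295 with an estimated correlation), including Ms4a1, which encodes CD20 (−4.49 and −3.73). Of 20 macrophage markers 10 and 14 fell, with medians of −0.87 and −1.66 and Csf1r at −3.0 and −3.83 (adjusted p = 0.0271 and 0.00194, and adjusted p = 0.388 and 0.295 with an estimated correlation). The wild-type macrophage call was lost without wild-type naive replicate 2. Of 15 granulocyte markers 10 fell in the knockout, with a median of −2.44 and Ngp at −5.0 (adjusted p = 0.0113, and adjusted p = 0.372 with an estimated correlation), against a median of −0.35 in wild-type cells (adjusted p = 0.826). Of 9 CD4 and regulatory T cell markers 5 and 6 rose, with medians of 2.25 and 1.34 and Ctla4 at 4.61 and 5.32 (adjusted p = 0.00452 and 0.00567, and adjusted p = 0.115 and 0.125 with an estimated correlation). Of the 11 entries fixed for that list 4, among them Ctla4 and Il2ra, also stood in the activation or inhibitory receptor lists. Its rise therefore need not come from other cells. Of 11 platelet markers 2 and 4 rose (2 and 6 adjusted over the list alone), with medians of 0.42 (adjusted p = 0.178) and 0.95 (adjusted p = 0.0319, and adjusted p = 0.146 with an estimated correlation), with the platelet chemokine Pf4 at 4.18 and 5.04.

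The other lists did not pass on activation in either genotype, although members moved both ways. Of 28 cytotoxic genes 13 and 15 rose and 9 and 10 fell (medians 0.60 and 1.34, adjusted p = 0.0557 and 0.0706), with Ifng at 4.50 and 6.10 and Ccl5 at −4.50 and −5.50. Of 28 effector transcription factors 11 rose in each (adjusted p = 0.107 and 0.102), with Irf4 at 4.85 and 4.75. Of 35 immediate early genes 11 and 15 rose and 18 and 11 fell (medians −0.80 and 0.15, adjusted p = 0.0961 and 0.236). Innate-like genes had medians of −0.03 and 0.19 and means of 0.20 and −0.35 (adjusted p = 0.533 and 0.665). Inhibitory receptors had medians of 0.22 and −0.11 (adjusted p = 0.104 and 0.364), with Pdcd1 at 3.70 and 2.07, and CDK inhibitors 0.95 and 0.02 (0.104 and 0.301). Mitochondrial genes had medians of −0.17 and 0.09 (0.512 and 0.573), and apoptosis regulators 0.02 and −0.10 in upward tests (0.628 and 0.823). ETS family genes had medians of −0.40 and −0.37 (0.296 and 0.368) and X-linked neighbours 0.45 and 0.74 (0.25 and 0.0745). NK cell markers had medians of −0.36 and −1.30 (0.826 and 0.105), dendritic cell markers −0.54 and −0.74 (0.232 and 0.199) and erythroid markers 0.41 and 0.49 (0.0791 and 0.199).

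The difference of the genotype effect between the states equally compares the activation effect between the genotypes. It tested whether the genotype effect differed between naive and activated arrays. Sex, array series and RNA integrity also differ between the states. Only additive effects of these cancel, so a difference cannot be credited to activation alone. Jun showed a difference of 2.60 on the log2 scale (SE 0.35, adjusted p = 0.0335), lower in naive knockout cells and not past the threshold in activated ones (306 against 234). Il24 showed 3.31 (SE 0.35, adjusted p = 0.0127) and Lad1 −3.29 (SE 0.31, adjusted p = 0.00681). Mki67 showed −2.30 (SE 0.29, adjusted p = 0.0225), having risen less on activation in the knockout from a higher start. Klf2 gave −1.21 (adjusted p = 0.134). In all 16 probe sets for 12 genes passed, 5 with a positive and 11 with a negative difference, and 2663 had an unadjusted p under 0.05, where 1367 were expected by chance. The limma count was 26 with an offset of 64 or with robust estimation, 30 with array weights and 0 without a trend (2321 unadjusted) or with the Actb ratio as a covariate (1314 unadjusted). It was 60 and 84 without wild-type naive replicates 1 and 2, 40 and 7 without knockout naive replicates 1 and 2, and 3 without knockout activated replicate 2. It was 0 without wild-type activated replicate 1 (1965 unadjusted), wild-type activated replicate 2 (1949) or knockout activated replicate 1 (2153). Of 30 lists 10 passed camera with the preset correlation, 0 with an estimated correlation and 4 with fry. Immediate early genes had the most positive median, 1.23 (adjusted p = 1.52e-24, and adjusted p = 0.0524 with an estimated correlation), with 24 members higher and 1 lower adjusted over the list alone.

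**Figure D3:**
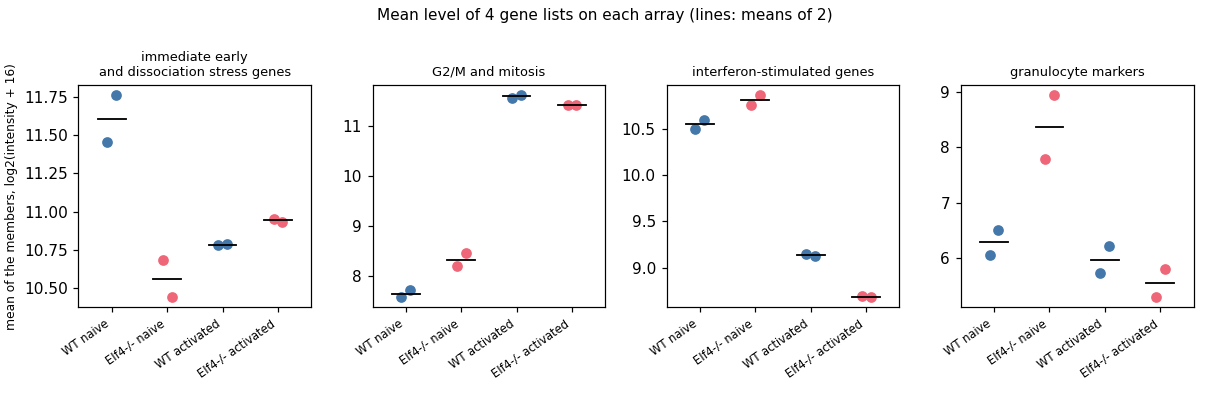
Mean of log2(intensity + 16) over the members of 4 gene lists on each of the 8 arrays, with 1 point per array (blue for wild type, red for knockout) and lines at the means of 2. Immediate early genes read 11.5 and 11.8 in naive wild-type and 10.7 and 10.4 in naive knockout arrays; mitotic genes and granulocyte markers were higher in naive knockout arrays, and interferon-stimulated genes lowest in activated knockout arrays.

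The genotype comparisons in the separate states, which also differ in sex, array series and RNA integrity, shared few calls, though more than independent lists would. The small number does not show that the effects differ. In the simulation only 24% (naive) and 20% (activated) of probe sets changed by 1 were recovered, and the interaction test called 16 probe sets. Of the 154 and 59 probe sets, 7 passed in both with the same sign, 5 higher and 2 lower, where independent lists would share 0.097 and 0.07, and 1 passed with opposite signs. Across all probe sets the log2 fold changes correlated at r = 0.09 and rho = 0.083, with no array shared. The named genes with the same sign were Scd2 (3.59 and 4.19), Ikzf2 (1.88 and 0.97) and Erdr1 (−6.01 and −5.85). Il24 was lower in naive (−1.43) and higher in activated knockout cells (1.88). The shared count was 3 without a trend or with the Actb ratio as a covariate, 4 without wild-type activated replicate 1 or knockout activated replicate 2, 13 without wild-type naive replicate 2 and 11 without knockout naive replicate 1.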

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

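The tests weighed in this part, on immediate early and mitotic genes, were chosen only after the results were seen, while the test of a difference between states was planned. The results below were selected because that interaction test passed, that is, the effect of the knockout in activated cells minus its effect in naive cells differed from 0. Sex, array series and RNA integrity change with the state, so the test does not separate activation from them. No group held enough arrays for a test of a sample far from its group.

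Among genes, Il24 had a difference of 3.31 on the log2 scale (adjusted p = 0.0127), with intensities of 62.8 and 13.3 in naive and 964 and 3575 in activated wild-type and knockout cells. Jun had 2.60 (adjusted p = 0.0335), the NF-κB inhibitor gene Tnfaip3 2.19 (0.0471), the endoplasmic reticulum chaperone gene Dnajb9 1.85 (0.0335) and the cytokine signalling inhibitor gene Socs3 1.82 (0.0225). Each of these 4 had a lower mean in naive knockout than in naive wild-type cells, for example 2250 against 8682 for Tnfaip3, and a higher mean in activated knockout cells. In the other direction S100a8 had −6.06 (adjusted p = 0.0483) and Igha −5.48 (0.0127), each with its high value in naive knockout cells alone. Lad1 had −3.29 (adjusted p = 0.00681), Mki67 −2.30 (0.0225), Ifi209 −2.08 (0.0225) and Ccdc50, an adaptor of receptor signalling, −2.07 (0.0225). Ifi209 read 5682 and 6134 in naive but 354 and 79.3 in activated wild-type and knockout cells. A brighter Ifi209 probe set, which read 9761 and 5070 in naive cells, gave −0.64 (adjusted p = 0.497), and the other Ccdc50 probe sets gave −0.36 to −0.54 without passing. The calls of Tnfaip3 and S100a8 were kept in 8 of 21 and 9 of 19 alternatives, both lost with quantile normalization and no filter, and those of the other 9 genes in 12 to 16 of 20 or 21.

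Among lists, immediate early genes had a median difference of 1.23 (adjusted p = 1.52e-24, and adjusted p = 0.0524 with an estimated correlation). Granulocyte markers had −2.58 (adjusted p = 6.18e-07, and adjusted p = 0.266 with an estimated correlation), NK cell markers −1.01 (0.000748, and 0.292) and platelet markers 0.52 (0.0418, and 0.266). The platelet call was kept in 6 of 17 alternatives, and was lost with quantile normalization and without any of 7 of the 8 arrays. Mitotic genes had −0.85 (adjusted p = 1.21e-13, and adjusted p = 0.106 with an estimated correlation), with Mki67 lower and 17 lower adjusted over the list alone. DNA replication genes had −0.29 (0.000644, and 0.124). Interferon-stimulated genes had −0.69 (adjusted p = 1.12e-11, and adjusted p = 0.0524 with an estimated correlation), with 13 lower adjusted over the list alone. Innate-like genes had −0.59 (adjusted p = 0.00037, and adjusted p = 0.106 with an estimated correlation), glycolysis 0.21 (0.00192, and 0.337) and the respiratory chain 0.13 (0.00983, and 0.57), whose call was kept in 10 of 17 alternatives. None of these lists kept its call with an estimated correlation.

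In naive knockout cells 14 of 35 immediate early genes fell and the list median was −1.12. The call was lost with an estimated correlation (adjusted p = 0.0956) and kept with fry (adjusted p = 0.0216). A lower share of T cells in the knockout preparations was argued against by the T cell receptor list, whose median was −0.02 with an SD of 0.22 over its 29 members. RNA quality stays open. With the Actb ratio as a covariate the list's median was −1.04 (adjusted p = 1.56e-24 at the preset correlation). Beside group means, the covariate's slope rests on gaps between replicates, mainly 7.44 against 11.1 in activated knockout cells. It does not decide the question in naive cells, where the ratio was 2.13 and 2.5 in wild-type and 1.99 and 1.96 in knockout arrays. Handling time or temperature before RNA extraction may raise such genes and stays open: the means of the list differed by 0.31 between the wild-type naive arrays and by 0.77 between the nearest arrays of different genotype, but the labels give no handling times. Loss of Elf4 also stays open, and the design does not separate it from handling or RNA quality.

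In naive knockout cells 7 of 50 mitotic genes rose and the list median was 0.72. The call was lost with an estimated correlation (adjusted p = 0.188) and kept with fry (adjusted p = 0.0226). RNA quality stays open. The median was 0.65 with the Actb ratio as a covariate (adjusted p = 1.08e-12 at the preset correlation). That does not decide it, because the covariate's slope rests mainly on the gap between the activated knockout arrays. Dividing cells of the granulocyte lineage could bring mitotic transcripts and stay open, since the granulocyte list was 1.14 higher in knockout naive replicate 2 than in replicate 1 and the mitotic list 0.26 higher, and 2 arrays do not decide whether they go together. Dividing cells of other types were not weighed and stay open. NK cell, macrophage and B cell markers had naive medians of 1.04, 0.72 and 0.55, against −0.09 for erythroid and −0.30 for platelet markers. The B cell list mean was 9.58 and 10.7 in the knockout and 9.78 and 9.59 in the wild-type naive arrays. A larger share of dividing T cells, the biological explanation, stays open too, because the DNA replication list had a median of −0.01 over members that went both ways. These explanations cannot be told apart from bulk RNA of 2 arrays.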

How the results depend on the processing

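The Actb covariate, the removal of probe sets that may cross-hybridise and the crossed block were chosen after the data were seen, and the other alternatives were planned. A change of direction was counted only where the main fit or the alternative passed. Over all named genes and alternatives 3398 results kept their side of the threshold, 493 fell short of it, 13 newly passed and 1 changed direction. Over the lists 2361 kept their side, 118 fell short, 69 newly passed and 2 changed direction. The results that kept their side may include changes of direction where neither fit passed. For every changed result below the cause was not tested, unless fewer arrays or genes give it.

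The naive count of 154 became 102 without a filter, 3 without a trend, 5 with the 4 naive arrays, 57 with array weights and 18 with the Actb ratio as a covariate. The activated count of 59 became 31 with median centring, 7 without a trend, 92 with robust estimation, 734 with the 4 activated arrays, 438 with array weights, 26 with the replicate number as a block and 6 with the Actb ratio. The residual SD was 0.514 in the fit of the naive and 0.435 in that of the activated arrays, and the array weights were lower for naive (0.675 in wild type, 0.829 in the knockout) than for activated arrays (1.356 and 1.318). The interaction count of 16 became 26 with an offset of 64, 26 with robust estimation, 30 with array weights, and in limma 0 without a trend (2321 at an unadjusted p under 0.05) and 0 with the Actb ratio (1314). The activation counts became 484 in wild type and 0 in the knockout with the Actb ratio (2622 at an unadjusted p under 0.05). The 7 probe sets shared between states became 3 without a trend and 3 with the Actb ratio.

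Lists past the threshold with an estimated correlation were 0 in naive, 0 in activated, 8 and 7 on activation in wild type and knockout and 0 for the interaction, and with fry 5, 2, 26, 28 and 4. With the Actb ratio 4 lists passed in activated cells. A Cd44 probe set that rose on activation of the knockout gave −0.224 with the Actb ratio (adjusted p = 0.982).

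Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 27 to 235 in naive and 8 to 103 in activated cells. It gave 0 to 84 for the interaction, with 1965 at an unadjusted p under 0.05 in limma where it was 0 without wild-type activated replicate 1. The shared count was 4 to 13, and 4 to 11 lists passed in naive cells. The activation counts, 7746 to 10849 and 8458 to 12184, stayed within 1.5 times. The B cell list ranged from −0.168 without knockout naive replicate 2 to 1.15 without knockout naive replicate 1 in naive cells, and from 0.426 to −1.058 for the interaction in the same order.

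The replicate numbers do not pair arrays: deviations of arrays with the same number correlated at −0.167 between the naive groups, 0.023 between the activated groups and −0.036 to 0.069 otherwise. With the number as a block 108 passed in naive cells and 14 for the interaction, and with the title label as a block 10170, 10974 and 21 on activation and for the interaction. The crossed block, with naive replicate 1 of the knockout set beside replicate 2 of the wild type, called 167 in naive cells. Signal over background limits dim genes: array medians were 63.9 to 86.0 against a target of 500, and the offset of 16 shrinks changes near that floor.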

Other observations

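The genes of the next paragraph, the share on chromosome 1 and the test of another strain's genome were chosen only after the results were seen. The tests of co-regulated neighbours and of shared probes were written before theirs.

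In activated cells the fit of those 4 arrays alone called 734 probe sets, 451 higher and 283 lower, for 577 genes. The genes below were chosen after their values were seen, no enrichment of any group was tested, and none of them passed in the fit of 8 arrays. Il13, a type 2 cytokine, read 315 and 403 in wild-type and 1273 and 1353 in knockout cells (log2 1.83, adjusted p = 0.0663 in the fit of 8 arrays and 0.00128 with 4). Il17a read 319 and 207 against 1262 and 1262 (log2 2.23, adjusted p = 0.144 and 0.00137). Il5 gave 2.44 (adjusted p = 0.214 and 0.036), Il9 1.38 (0.265 and 0.0369), the T cell growth factor Il2 1.19 (0.298 and 0.00714) and Il3 1.10 (0.337 and 0.0126). Il4 gave 0.41 (adjusted p = 0.889 and 0.506), Il10 0.83 (0.544 and 0.214), Csf2 0.58 (0.604 and 0.0829) and Ifng 0.25 (0.841 and 0.315). Tbx21, which drives type 1 responses, gave −0.63 (adjusted p = 0.163 and 0.0278), and Gata3, which drives type 2 responses, 0.66 (0.241 and 0.0527). The NK receptor genes Klrc1 and Klrd1 gave −1.21 (adjusted p = 0.118 and 0.00163) and −0.74 (0.0891 and 0.015), and Cd69 −0.64 (0.203 and 0.0248).

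Genes called in activated cells lay near each other more often than random genes. Of 44 genes 14 had a called neighbour among the next 20 tested genes, where random sets had a median of 6 and as many in 0.82% of draws. On chromosome 1 lay 13 of the 44 called genes (29.5%), against 5.7% of 12795 tested genes (Fisher's exact p = 6.39e-07). That p is not adjusted for the choice of this chromosome and treats neighbouring genes as independent. Pairs of neighbours were Ap1s3 and Wdfy1, R3hdm1 and Il24, Rnpep and Lad1, Atp1b1 and Xcl1, and Ifi209 and Mndal on that chromosome, Uri1 and Pop4 on chromosome 7 and Armcx2 and Bex1 on the X chromosome. Of the 128 genes called in naive cells 10 lay on chromosome 1 (7.8%, Fisher's exact p = 0.334), and 52 had a called neighbour, with as many in 7.01% of random sets.

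Probes shared between paralogs as the whole cause of the neighbouring calls were argued against. Calls of probe sets that may cross-hybridise were dropped from the main fit without refitting, which left 34 called genes. Of these 10 had a called neighbour, with as many in 1.38% of random sets. Stretches of another strain's genome carried in the knockout line stay open: the 14 genes with a called neighbour prompted the idea and do not test it, and the 52 of the naive calls lay between the median of random sets, 42, and their 95th percentile, 53. The X-linked neighbours of Elf4, a list fixed beforehand, had a median of 0.23 in activated cells. Camera gave adjusted p = 0.013 with the preset and 0.303 with an estimated correlation, and fry gave 0.017. In naive cells their median was 0.03 (camera adjusted p = 0.746), so they do not decide it either. Poor binding of probes to a variant would lower naive values too. There the probe sets of neighbouring genes that fell in activated cells gave mixed values: 0.00 and −0.25 for Mndal, 0.12 and −0.94 for Ifi209, 0.08 for Uri1, −0.19 for Pop4, −0.75 for Rnpep, −0.30 for Lad1 and 0.34 for Xcl1. Erdr1, which had no called neighbour, was lower in naive (−6.01) and activated knockout cells (−5.85) alike. Of the 7 probe sets past the threshold in both states with the same sign, 5 were higher and 2 lower. Co-regulated or duplicated neighbours, such as the related genes Ifi209 and Mndal, stay open, since random sets of genes called on activation (0.7% with as many, again a median of 6) hardly differed from those of all genes and so decide nothing. The labels do not give the strain in which the knockout was made, and loss of Elf4 as the biological explanation stays open for each of these genes.

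Several probe sets without a gene symbol passed in both states, with log2 changes of −6.77 and −5.65, 5.99 and 5.61, 2.49 and 3.06, and 2.53 and 3.0 in naive and activated cells. The Y-linked gene Kdm5d read 448 to 922 on naive and 2.56 to 35.5 on activated arrays. Of the genes called in naive cells 40 of 128 belonged to a list, and of those called in activated cells 8 of 44. The signal ratio of the 3' to the 5' probe set of Gapdh was 3.38 to 4.42 on naive and 4.83 to 7.56 on activated arrays.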
